A study of Mus musculus with 24 samples.

How the data were processed

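Poly(A) RNA-seq libraries from gingiva and from the dentoalveolar complex (DAC) of mice with ligature periodontitis were analysed, 4 per group and tissue: sham surgery (Sham), ovariectomy with vehicle (OVX) and ovariectomy with estradiol benzoate (OVXE2), 24 in all. The labels call the 4 libraries of a group biological replicates. They do not say whether each is a separate animal or whether both tissues came from the same mice, so no pairing was assumed. Per the submitters' processing notes, reads were trimmed with fastp, aligned with STAR to mouse genome build GRCm38 (mm10), and analysed with DESeq2. The versions, the DESeq2 design and the annotation release are not given in the sources used here.

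The deposited values used here are raw gene counts, 1 table per library, in the layout of STAR's gene quantification as the authors' notes name that aligner. Each table held 38321 gene IDs with counts for either strand, the sense strand and the opposite strand, and 4 lines of reads assigned to no gene. The opposite-strand column was used, since it held most reads in every library: the share on the other strand was 3.38 to 9.03%. That share, of reads on the strand opposite to the counted one, is called other-strand or opposite-strand share below. GENCODE M21 named 38186 of the IDs and gave the coordinates, and 16170 of its 22028 protein-coding genes were listed. Genes of a list or panel that were not listed are not analysed here. Of fragments, 0.495 to 1.04% were unmapped, 6.40 to 13.5% mapped to several places, 19.8 to 32.2% fell on no annotated feature and 0.872 to 1.19% were ambiguous. Genes with a count numbered 16830 to 17756 in gingiva and 17730 to 19142 in the DAC. No library was a copy of another of its group by their counts (chi-square per degree of freedom 20.0 to 439). Pairs across groups or tissues were not compared.

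Groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined, except where a statement below gives an addition. Counts were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3. The 12 libraries of a tissue entered 1 fit with 9 residual degrees of freedom, which left 12680 genes in gingiva and 13617 in the DAC. All 24 libraries entered the fit for the comparison of the tissues in Sham and for differences of effects between tissues, with 18 residual degrees of freedom and 14209 genes. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 0.164 in gingiva and 0.305 in the DAC. Log2 CPM used a prior count of 2. CPM are TMM-scaled within a tissue, except in the comparison of tissues, where all 24 libraries were scaled together.

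In total, 42 lists of cell type, pathway and estrogen-response genes with 766 symbols were fixed, of which 564 were found, and those with at least 5 measured members were tested (42 in the DAC and 41 in gingiva). The test was camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives. An estimated correlation allows for members that vary together between libraries, so each result with the preset value is given with it. Adjustment over the members of a list alone is given beside adjustment over all genes. Mean log2 CPM of a list was compared between groups by exact permutation of 4 against 4 libraries (70 relabellings). For the B lymphopoiesis and immature neutrophil lists this was repeated within sets of libraries alike in nasal-gland, brain neuron or other-strand share (30 to 40 relabellings), a test added after the data were examined. The share of variation between groups was computed over the 5000 genes of highest variance, with 100000 relabellings. The share of opposite signs was set against simulated unchanged groups that share libraries; its threshold of an unadjusted p under 0.01 was chosen after no gene had passed between OVX and Sham.

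Genes were named by rule: of genes past the test with the 4 values of a group all above those of the other, a mean of at least 1 log2 CPM and a name other than a predicted or receptor-segment gene, the 10 with the largest rise and the 10 with the largest fall. Where fewer than 6 passed, the 6 with the smallest p were taken as values. From each list that passed or held called members up to 4 called genes were taken, or up to 2 as values. A panel of 16 genes was followed in every comparison, of which 12 were listed. For differences between tissues the 10 genes with the smallest p were taken. The report prints a part of these genes, mainly those that kept their call without each library; a few genes that the rule takes are not reported here.

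The gene and list tests were tried on counts simulated with the design and depth of these libraries. For the gene test, genes changed by 1.5, 2 or 4-fold. In gingiva 53.7, 80.6 and 97.0% were recovered for OVX against Sham (12544 genes), 56.7, 77.6 and 98.5% for OVXE2 against OVX (12531 genes) and 61.2, 80.6 and 98.5% for OVXE2 against Sham (12547 genes). In the DAC these were 28.4, 65.7 and 89.4% (13393 genes), 32.8, 70.1 and 93.9% (13389 genes) and 22.4, 61.2 and 92.4% (13395 genes). For the difference between tissues 22.4, 49.3 and 86.4% were recovered for OVX against Sham and 26.9, 47.8 and 86.4% for OVXE2 against OVX (14055 genes each), and 40.3, 77.6 and 89.4% for the tissues in Sham (13850 genes). Of the calls, 3.60 to 4.91% were unchanged genes. A raised list was called with 0 other lists. Every gene was drawn independently here. The rates of recovery and of false calls therefore do not cover genes that vary together, as members of a list can in real libraries. The group share test was tried apart, on independent normal values rather than counts. It gave a p under 0.05 in 6.5% of 200 simulations without a shift. With a part of the genes shifted by 1 SD in OVXE2 it did so in 100%. Its power in libraries such as these was not measured.

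Alternatives were DESeq2 1.42.0, limma-voom with quality weights, a surrogate variable from sva 3.50.0, RLE and upper quartile scaling, and no low-count filter. Others were a filter of 5 CPM in 4 libraries, replicate number as a block and a fit of the compared groups alone. Each library was also left out in turn. Genes past the usual test were counted as well with an estimated change of at least 2-fold. Added after the data were examined were the counts of either strand, the other-strand share as a covariate, the libraries with a share above 5% alone, leaving out the shallowest DAC library (Sham 2) with the one richest in nasal-gland transcripts (OVX 1), leaving out the 4 DAC libraries with most counts of brain neuron markers (Sham 2, OVX 1, OVXE2 1 and OVXE2 2), and a block for each group and replicate number. The mean levels of a few further marker lists, for glands of the nose, neurons of the brain, olfactory epithelium and peripheral ganglia, were also added then.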

Results

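The study asked how the loss and the replacement of estrogen change gene expression in the tissues around teeth with ligature-induced periodontitis. Gene counts were analysed from 24 poly(A) RNA-seq libraries of female mice that all carried a silk ligature around the maxillary second molars. The mice had sham surgery (Sham), ovariectomy followed by vehicle (OVX), or ovariectomy followed by daily estradiol benzoate (OVXE2). Gingiva, the soft tissue around the teeth, and the dentoalveolar complex (DAC), the alveolar bone with its teeth after removal of soft tissue, each gave 4 libraries per group. The total gene count per library ran from 18598422 to 26001342 in gingiva and from 14771830 to 29248358 in the DAC. Sham libraries of the DAC were the shallowest, with 14771830 to 24923126 gene counts, against 24341708 to 29248358 in OVX and 23697984 to 27302805 in OVXE2. Keratin 13 (Krt13) took the largest share of counts in every gingival library, and type I collagen (Col1a1) did so in every DAC library but 1: in replicate 1 of the OVX group the nasal secretory gene Bpifb9b held 9.43% of counts.

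In the DAC, estradiol after ovariectomy went with much lower transcripts of B cell precursors and of immature marrow neutrophils and with higher transcripts of endothelium and of a few other genes such as A2m and Pi15. Of 13617 genes tested between OVXE2 and OVX, 92 rose and 198 fell. The largest falls were those of B cell precursors. Vpreb3, a partner of the pre-B cell receptor (ENSMUSG00000000903, chromosome 10, 75943057 to 75949657, GRCm38), stood at 2.44 ± 0.263 CPM (SD, n = 4) in OVXE2 and 20.9 ± 4.57 CPM in OVX, a log2 change of −3.10 ± 0.18 (SE) with an edgeR adjusted p of 1.06e-05. The recombinase gene Rag1 (ENSMUSG00000061311, chromosome 2, 101638282 to 101649501) stood at 1.75 ± 0.923 CPM against 19.6 ± 7.04, a log2 change of −3.48 ± 0.43 with an adjusted p of 0.00167. The largest rises were those of A2m, the protease inhibitor alpha-2-macroglobulin, Pi15, a secreted peptidase inhibitor, and Trpc6, a calcium-permeable channel.

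A2m (ENSMUSG00000030111, chromosome 6, 121635376 to 121679227) stood at 63.2 ± 11.3 CPM (SD, n = 4) in OVXE2 and 5.17 ± 1.58 CPM in OVX, a log2 change of 3.60 ± 0.22 (SE) with an edgeR adjusted p of 1.06e-05. Pi15 (ENSMUSG00000067780, chromosome 1, 17601901 to 17630939) rose from 4.73 ± 2.02 to 47.9 ± 10.1 CPM, and Trpc6 (ENSMUSG00000031997, chromosome 9, 8544142 to 8680741) from 6.01 ± 1.24 to 32.2 ± 5.55 CPM. Smaller rises were those of Aldh1a2, which makes retinoic acid, from 13.7 ± 2.3 to 38.5 ± 3.9 CPM, and of Asb4 and Plppr5, with log2 changes of 1.62 and 1.42. The teneurin gene Tenm4, a regulator of osteoblast and oligodendrocyte differentiation, rose by 1.26 and the pacemaker channel gene Hcn4 by 1.28 on the log2 scale. Pgr, the progesterone receptor and a classical estrogen target, rose from 0.806 ± 0.388 to 4.18 ± 1.75 CPM, with an adjusted p of 0.0183. The call of Pgr was lost without replicate 3 or 4 of OVX or replicate 1 of OVXE2, with an adjusted p of up to 0.0661.

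Of 42 lists 8 were higher and 13 lower with a preset correlation, 5 passed with an estimated correlation and 8 with fry. Among them, that for B lymphopoiesis moved furthest: 10 of its 12 members fell, the median log2 change was −2.56, and all 12 passed when adjusted over the list alone (adjusted p = 0.00012 with an estimated correlation). Besides Vpreb3 and Rag1 these were the B cell identity factor Pax5, from 25.3 ± 4.97 to 3.2 ± 1.22 CPM (SD, n = 4), Rag2, and the antigen receptor subunits Cd79a and Cd79b, with log2 changes of −2.71 and −2.41. Of 11 genes of mature B and plasma cells 5 fell, 7 when adjusted over the list alone, with a median of −1.38 (adjusted p = 0.00373 with an estimated correlation). The median of this list was −0.85 without OVX 3, and its adjusted p with an estimated correlation was 0.101 in the libraries of higher opposite-strand share (range over all alternatives 0.00314 to 0.101). The B cell coactivator Pou2af1 (ENSMUSG00000032053, chromosome 9, 51213708 to 51240080) fell from 32.4 ± 1.28 to 4.69 ± 1.02 CPM, and the intracellular Fc receptor-like gene Fcrla fell with a log2 change of −2.73. The transcription factor gene Spib, also used by B cells, fell from 45.4 ± 4.07 to 7.86 ± 2.23 CPM. Of 11 genes of immature marrow neutrophils 9 fell and 11 did when adjusted over the list alone, with a median of −1.60 (adjusted p = 0.00959 with an estimated correlation). That call was lost in the libraries of higher opposite-strand share and without the 4 DAC libraries with most brain neuron counts. The primary granule enzymes myeloperoxidase (Mpo, ENSMUSG00000009350, chromosome 11, 87793581 to 87804413) and neutrophil elastase (Elane, ENSMUSG00000020125, chromosome 10, 79886247 to 79888215) fell from 380 ± 57.4 to 103 ± 24.7 CPM and from 154 ± 31.2 to 47.3 ± 9.88 CPM. Cathepsin G (Ctsg) and the ficolin gene Fcnb fell with log2 changes of −1.85 and −2.38.

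Dendritic cell genes were lower as well. All 7 genes of dendritic cells and antigen presentation were lower in OVXE2, 3 of them past the test, also when adjusted over the list alone: Ccr7, which guides dendritic cells to lymph nodes, the lectin gene Cd209a and the cytokine receptor gene Flt3 fell with log2 changes of −1.89, −1.82 and −1.05 (adjusted p = 0.0304 with an estimated correlation). That list missed 0.05 with an estimated correlation without Sham 4, OVX 1, OVX 3, OVX 4, OVXE2 1, OVXE2 2 or OVXE2 4, with an adjusted p of up to 0.0989, and in the libraries of higher opposite-strand share, with 0.173 (range over all alternatives 0.0187 to 0.173). Of 17 T cell and NK cell genes 16 were lower, 3 passed over all genes and 11 when adjusted over the list alone, with a median of −1.18 (adjusted p = 0.0832 with an estimated correlation). Without each library in turn that adjusted p ran from 0.0270 to 0.175 and was below 0.05 for 2 of 12. The cytotoxic granule gene Nkg7 fell from 17.4 ± 1.73 to 4.02 ± 1.28 CPM (SD, n = 4), and the adhesion receptor gene Cd2 fell with a log2 change of −2.07. Ccr2, the receptor that draws monocytes out of marrow, fell from 71.0 ± 16.9 to 28.3 ± 3.99 CPM and was the single called member of the 10 of the monocyte and macrophage list, 2 when adjusted over the list alone, which had a median of −0.02 (adjusted p = 0.499 with an estimated correlation). Genes of erythroid cells were lower in 12 of 12 cases, with a median of −0.65 and no member past the test, also when adjusted over the list alone (adjusted p = 0.482 with an estimated correlation). Mature neutrophil genes lay lower in 11 of 13 cases, with a median of −0.39 and no member past the test, 3 lower and 1 higher when adjusted over the list alone (adjusted p = 0.442 with an estimated correlation).

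Endothelial genes moved the other way. Of 15, 14 were higher in OVXE2, 4 passed and 10 did so when adjusted over the list alone, with a median of 0.45 (adjusted p = 0.0288 with an estimated correlation). VE-cadherin (Cdh5, ENSMUSG00000031871, chromosome 8, 104101625 to 104144511) rose from 174 ± 11.1 to 258 ± 24.7 CPM (SD, n = 4) and the receptor gene Tie1 from 109 ± 10.9 to 155 ± 9.11 CPM. The result with an estimated correlation missed 0.05 without OVX 1, OVX 3, OVXE2 2, OVXE2 3 or OVXE2 4, up to an adjusted p of 0.0813, and in the libraries of higher opposite-strand share, with 0.239 (range over all alternatives 0.00911 to 0.239). Of 9 genes of smooth muscle and pericytes 2 rose, 3 when adjusted over the list alone (adjusted p = 0.158 with an estimated correlation), among them the pericyte gene Rgs5, from 500 ± 20 to 693 ± 44.1 CPM. Osteoclast genes were higher in 10 of 11 cases, with a median of 0.36. None passed over all genes, while 8 higher and 1 lower did when adjusted over the list alone (adjusted p = 0.356 with an estimated correlation). The osteoclast receptor gene Oscar and the gelatinase gene Mmp9 changed by 0.43 ± 0.12 and 0.40 ± 0.12 (log2, SE), with adjusted p of 0.105 and 0.150, and the resorption enzymes Ctsk and Acp5 by 0.36 and 0.47, with adjusted p of 0.354 and 0.438. The fibronectin gene Fn1 rose by 0.71 on the log2 scale and lost its call without OVX 3, with an adjusted p of 0.0655. The bone sialoprotein gene Ibsp stood at an adjusted p of 0.0487 and missed 0.05 without any 1 of the 12 libraries, up to 0.149.

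Of the 16 estrogen-responsive genes 7 were higher and 9 lower in the DAC of OVXE2 than of OVX. Their median log2 change was −0.10 (−0.17 without OVX 1 or OVXE2 3, −0.05 without OVX 4, OVXE2 1 or OVXE2 2). The adjusted p was 0.0604 by the preset correlation (below 0.05 without Sham 4 or OVXE2 2, down to 0.0388), 0.260 with an estimated correlation and 0.0327 with fry (range with fry over all alternatives 0.0155 to 0.127). Pgr rose, as did the secreted glycoprotein gene Stc2, by 0.61 on the log2 scale. Myb, a transcription factor gene of blood progenitors, fell from 40.2 ± 3.92 to 8.77 ± 2.7 CPM (SD, n = 4), and the granule protein lactoferrin gene Ltf, also a gene of immature neutrophils, and the estrogen receptor gene Esr1 fell with log2 changes of −1.20 and −0.56. When adjusted over the list alone 2 passed upward and 4 downward. The call of Stc2 was lost without OVX 1, OVX 4 or any OVXE2 library, up to an adjusted p of 0.0834, that of Ltf without 9 of the libraries (Sham 1, Sham 3, OVX 1, OVX 2, OVX 4 and each OVXE2 library), up to 0.114, and that of Esr1 without any library but OVXE2 2, up to 0.160. The RANKL gene Tnfsf11, the cytokine genes Il17a, Il1b and Il6, and the bone genes Bglap, Col1a1 and Sost had log2 changes of 0.06, −0.54, −0.16, 0.15, −0.11, −0.03 and 0.03, none past the test. The neutrophil alarmin gene S100a8 changed by −0.69 ± 0.26 (log2, SE), with an adjusted p of 0.329.

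The count of 290 genes was 186 without OVX 4, 178 without OVXE2 1 and 176 without OVXE2 4. Of the 55 called genes that the naming rule gave, 37 kept the call without each of the 12 libraries in turn. Of the 290, 147 had an estimated change of at least 2-fold. With DESeq2 598 genes passed, with limma-voom 443, with a surrogate variable 583, and when only the OVX and OVXE2 libraries were fitted 189. The libraries fell into a lower and a higher set by the share of reads on the strand opposite to the counted one. Among those of the higher set alone 39 genes passed, all of them among the 290, and each of the 290 kept its sign. Markers of nasal glands made up 14.0% of counts in the richest OVX library (replicate 1) and 4.15 ± 6.62% (SD, n = 4) over the OVX group, against 0.727 ± 0.282% in OVXE2. Without that library and the shallowest one, 215 genes passed. Markers of brain neurons took 0.0261 and 0.0222% of counts in OVXE2 1 and OVXE2 2 and 0.0222% in OVX 1, the highest values of the 2 groups. Without these 3 libraries and Sham 2, which had the most, 37 genes passed, all of them among the 290, and each of the 290 kept its sign.

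**Figure D1:**
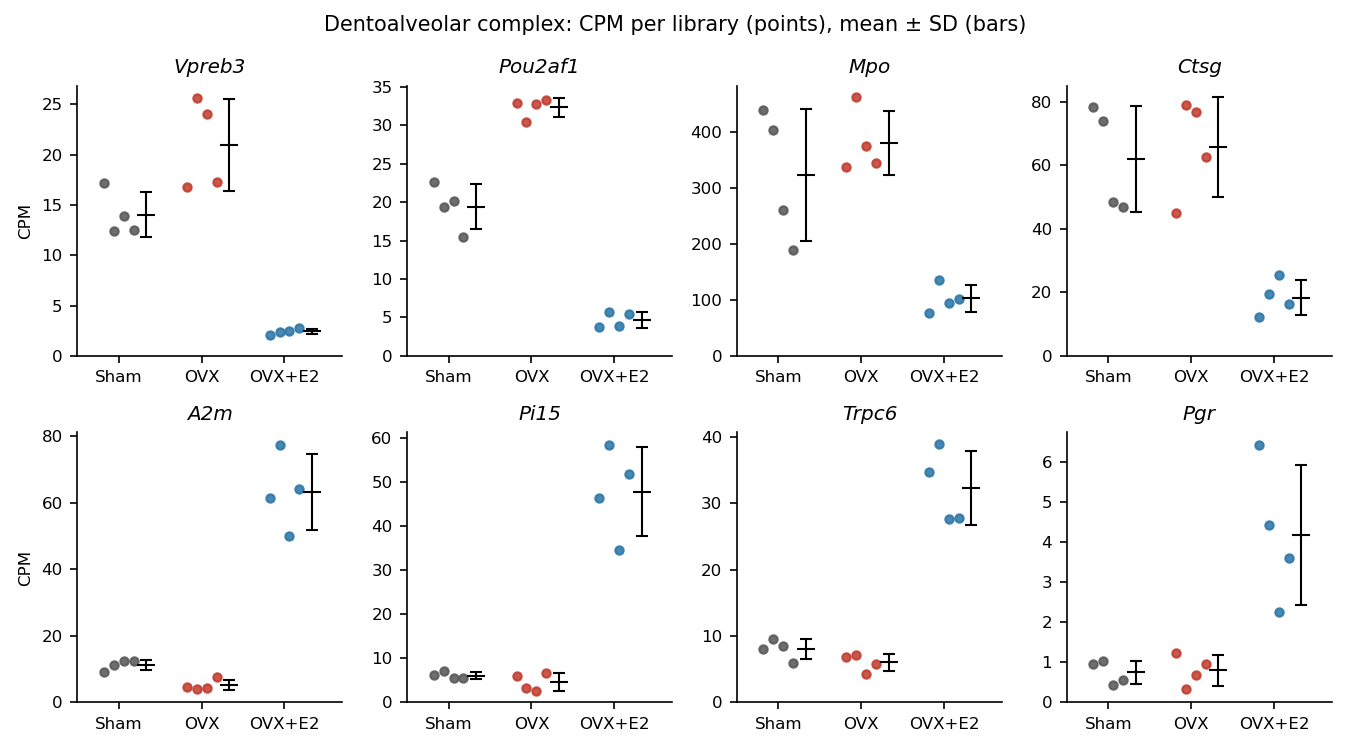
Expression of 8 genes in each DAC library, in CPM on a linear axis, by group (Sham, OVX, OVXE2). Points are the 4 libraries of a group and bars their mean ± SD. Vpreb3, Pou2af1, Mpo and Ctsg stood lower in OVXE2 (Vpreb3 2.44 ± 0.263 CPM against 20.9 ± 4.57 in OVX), and A2m, Pi15, Trpc6 and Pgr stood higher (A2m 63.2 ± 11.3 CPM against 5.17 ± 1.58).

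**Figure D2:**
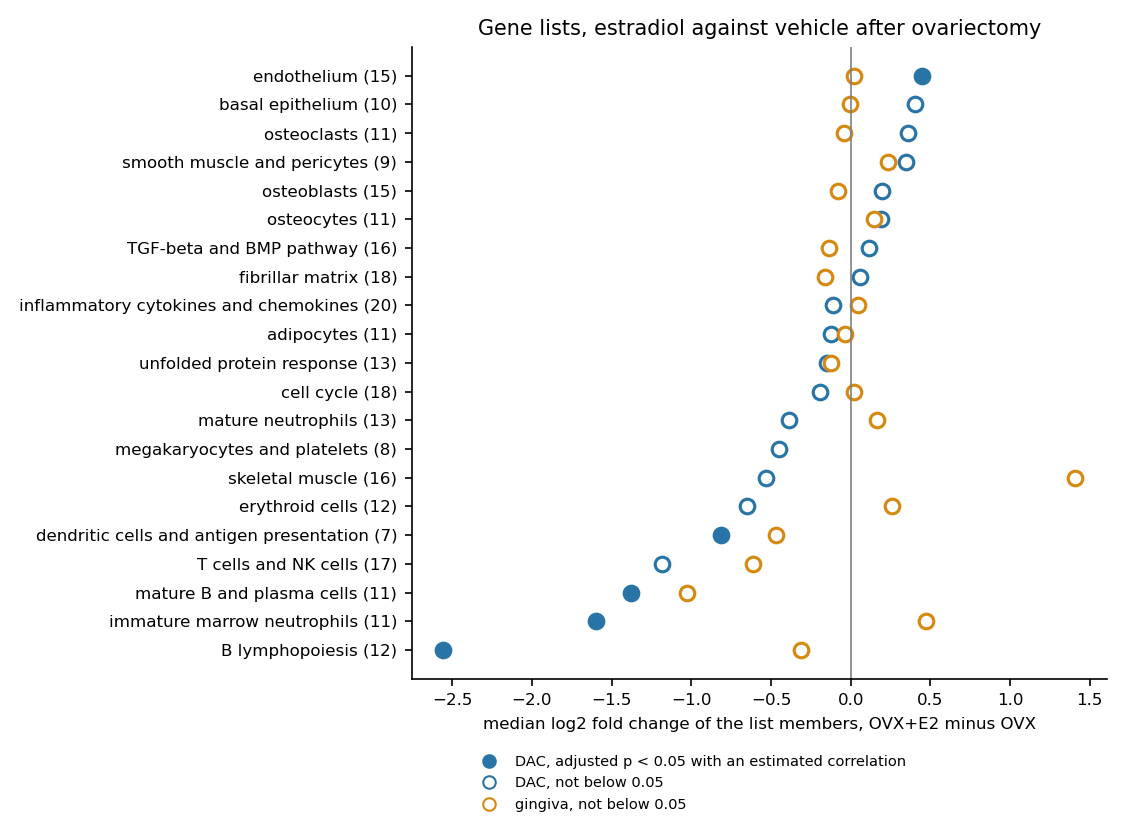
Median log2 fold change from OVX to OVXE2 of the 21 gene lists that passed with a preset correlation in the DAC, with the same lists in gingiva beside them. Filled symbols mark lists with an adjusted p under 0.05 with an estimated correlation. Only 5 lists did so, all in the DAC, with medians from −2.56 (B lymphopoiesis) to 0.45 (endothelium).

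Against Sham, the DAC of OVXE2 mice had lower transcripts of B cells and of immature neutrophils, the lists that passed with an estimated correlation. Those of dendritic cells and endothelium, which passed against OVX, missed it here, and the difference between these comparisons was not tested. Of 13617 genes 53 rose and 90 fell. Vpreb3 stood at 2.44 ± 0.263 CPM (SD, n = 4) against 14.0 ± 2.24 in Sham, a log2 change of −2.52 ± 0.18 (SE) with an edgeR adjusted p of 0.000149. Pou2af1 stood at 4.69 ± 1.02 against 19.4 ± 2.97 CPM and Mpo at 103 ± 24.7 against 323 ± 118 CPM. A2m stood at 63.2 ± 11.3 against 11.2 ± 1.57 CPM, Pi15 at 47.9 ± 10.1 against 6.1 ± 0.78 CPM and Trpc6 at 32.2 ± 5.55 against 8.02 ± 1.53 CPM. The lectin gene Mgl2 of alternatively activated macrophages and dendritic cells, not among the largest changes against OVX, rose from 8.66 ± 0.818 to 20.5 ± 1.03 CPM. The cystatin gene Cst7 and the monoacylglycerol acyltransferase gene Mogat2 fell with log2 changes of −2.02 and −1.96.

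Of 42 lists 7 were higher and 11 lower against Sham with a preset correlation, 3 passed with an estimated correlation and 4 with fry. Of the 12 B lymphopoiesis genes 8 fell in OVXE2 against Sham, 10 when adjusted over the list alone, with a median of −1.80 (adjusted p = 0.0018 with an estimated correlation, and 0.0765 without the 4 DAC libraries with most brain neuron counts, which leaves 2 of OVXE2; range over all alternatives 0.00104 to 0.0765). Pax5 and Cd79a fell with log2 changes of −2.05 and −1.94. Of the 11 immature marrow neutrophil genes 6 fell, 11 when adjusted over the list alone, with a median of −1.42 (adjusted p = 0.0218 with an estimated correlation, and 0.0858 without OVXE2 3, 0.106 without those 4 libraries, 0.0584 with replicate number as a block and 0.0657 in the libraries of higher opposite-strand share; range over all alternatives 0.00597 to 0.106). Besides Mpo, Fcnb and Ctsg fell with log2 changes of −2.0 and −1.76. Of the 11 genes of mature B and plasma cells 4 fell, also when adjusted over the list alone, with a median of −0.50 (adjusted p = 0.0276 with an estimated correlation, and up to 0.172 without Sham 3, Sham 4, OVX 1, OVX 2, OVX 4 or OVXE2 3, 0.0609 with replicate number as a block and 0.324 in the libraries of higher opposite-strand share; range over all alternatives 0.0199 to 0.324). Of 17 T cell and NK cell genes 16 were lower and 2 fell, 4 when adjusted over the list alone, with a median of −0.87 (adjusted p = 0.314 with an estimated correlation). One of them was Nkg7, from 12.9 ± 3.97 to 4.02 ± 1.28 CPM (SD, n = 4). Dendritic cell genes were lower in 7 of 7 cases and 3 fell, also when adjusted over the list alone, with a median of −0.55 (adjusted p = 0.0768 with an estimated correlation). Nerve and Schwann cell genes were lower in 12 of 12 cases with a median of −0.42, none of them past the test and 4 when adjusted over the list alone (adjusted p = 0.247 with an estimated correlation). Markers of peripheral ganglia, a list added after the data were examined, took 0.000722 to 0.0392% of counts in Sham, with the highest values in Sham 3 and Sham 4, and 0.00101 to 0.00143% in OVXE2. Endothelial genes were higher in 14 of 15 cases with a median of 0.19; 1 passed and 6 did when adjusted over the list alone (adjusted p = 0.208 with an estimated correlation).

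Pgr stood at 4.18 ± 1.75 CPM (SD, n = 4) in OVXE2 against 0.749 ± 0.293 in Sham, a log2 change of 2.48 ± 0.45 (SE) with an edgeR adjusted p of 0.0265. The call was lost without any Sham library or without OVXE2 1, OVXE2 2 or OVXE2 4, up to an adjusted p of 0.0958. Esr1, Tnfsf11, Il6, Ctsk and Acp5 had log2 changes of −0.22, −0.33, −0.58, 0.03 and 0.13, none past the test. The count of 143 genes was 61 without Sham 1, 89 without Sham 2, 79 without Sham 3 and 93 without Sham 4, and 74, 70 and 73 without OVXE2 1, OVXE2 2 and OVXE2 4. Of the 143, 74 had an estimated change of at least 2-fold. The count was 340 with DESeq2, 337 with limma-voom, 279 with a surrogate variable and 62 with the opposite-strand share as a covariate. It was 16 among the libraries of higher opposite-strand share and 10 without the 4 libraries with most brain neuron counts. With only the OVXE2 and Sham libraries fitted it was 64. Of 40 called genes given by the naming rule, 23 kept the call without each library in turn.

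Between OVX and Sham, no single gene of the DAC passed, and of the lists B lymphopoiesis alone did with an estimated correlation. In edgeR 0 of 13617 genes passed (smallest adjusted p 0.874), 437 had an unadjusted p under 0.05, DESeq2 called 8 higher and 2 lower and limma-voom 0. Of 42 lists 9 were higher and 11 lower with a preset correlation (13 lists in all without Sham 3), and 1 passed with an estimated correlation and with fry. All 12 B lymphopoiesis genes were higher in OVX, with a median log2 difference of 0.76. None passed over all genes and 10 did when adjusted over the list alone (adjusted p = 0.0236 with an estimated correlation). That result missed 0.05 without Sham 2, OVX 2, OVX 3 or OVXE2 2, up to an adjusted p of 0.163, and with replicate number as a block or in the libraries of higher opposite-strand share, with 0.159 and 0.182, and with 0.449 without the 4 libraries with most brain neuron counts (range over all alternatives 0.0217 to 0.449). The antigen receptor gene Cd79b stood at 43.4 ± 11.4 CPM (SD, n = 4) in OVX and 25.7 ± 6.29 in Sham, Pou2af1 at 32.4 ± 1.28 and 19.4 ± 2.97, and Spib at 45.4 ± 4.07 and 24 ± 3.93. All 11 genes of mature B and plasma cells were higher too, with a median of 0.70, none past the test and 5 when adjusted over the list alone (adjusted p = 0.125 with an estimated correlation).

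Other groups of the DAC differed between OVX and Sham in direction, and no member of them passed over all genes. Erythroid genes were higher in OVX in 12 of 12 cases with a median of 0.51 and T cell and NK cell genes in 16 of 17 with a median of 0.43, none of either when adjusted over the list alone (adjusted p = 0.457 with an estimated correlation for each). Nerve and Schwann cell genes were lower in 12 of 12 cases with a median of −0.48 (adjusted p = 0.457 with an estimated correlation). Markers of peripheral ganglia took 0.0166 and 0.0392% of counts in Sham 3 and Sham 4 and 0.0289% in OVX 1, against 0.000722 to 0.00257% in the other libraries of these groups. Osteoclast genes were lower in 10 of 11 cases with a median of −0.21 and none past the test when adjusted over the list alone (adjusted p = 0.464 with an estimated correlation). Oscar, Ctsk, Acp5 and Tnfsf11 had log2 differences of −0.38, −0.33, −0.35 and −0.39. Endothelial genes were lower in 13 of 15 cases with a median of −0.21 (adjusted p = 0.457 with an estimated correlation). A2m stood at 5.17 ± 1.58 CPM in OVX and 11.2 ± 1.57 in Sham, the smallest p of all genes, with a log2 difference of −1.11 ± 0.20 (SE) and an adjusted p of 0.874. The leukaemia inhibitory factor gene Lif, the cartilage proteoglycan gene Acan and the homeobox gene Alx4 followed, with log2 differences of −0.51, 0.64 and 0.67. Esr1, Pgr and Il6 differed by 0.34, 0.11 and −0.73, none past the test.

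In gingiva, no gene and, with an estimated correlation, no list passed between OVX and Sham. The mean values lay higher in OVX for neutrophil alarmins, T cell and matrix genes and lower for lipid synthesis genes. In edgeR 0 of 12680 genes passed between OVX and Sham, 1530 had an unadjusted p under 0.05, DESeq2 called 7 higher and 37 lower and limma-voom 0. The smallest p was that of S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035), at 1134 ± 140 CPM (SD, n = 4) in OVX and 687 ± 94 in Sham, a log2 difference of 0.72 ± 0.13 (SE) with an adjusted p of 0.376. Its partner S100a9 stood at 1613 ± 345 and 993 ± 148 CPM. The receptor gene Erbb3 and the peroxisomal carnitine transferase gene Crot differed by −0.29 and −0.30, and the leukocyte surface gene Cd52 by 0.62.

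Of 41 lists tested in gingiva, 12 were higher and 3 lower in OVX than in Sham with a preset correlation, and 0 passed with an estimated correlation or with fry. T cell and NK cell genes were higher in 14 of 15 cases with a median of 0.46 (adjusted p = 0.569 with an estimated correlation), with Cd3d 0.74 higher on the log2 scale. Genes of fibrillar matrix were higher in 18 of 18 cases with a median of 0.44, among them the proteoglycan gene Bgn with 0.54 (adjusted p = 0.706 with an estimated correlation). Lipid and cholesterol synthesis genes were lower in 12 of 12 cases with a median of −0.23, among them Lss with −0.34; 6 passed when adjusted over the list alone (adjusted p = 0.674 with an estimated correlation). Monocyte and macrophage genes were higher in 9 of 10 cases with a median of 0.45 and 3 past the test when adjusted over the list alone (adjusted p = 0.674 with an estimated correlation), and complement genes in 10 of 11 with a median of 0.38 and 3 past it (adjusted p = 0.706 with an estimated correlation). The complement genes C1qa and C1qb differed by 0.66 and 0.56. The interferon-induced chemokine genes Cxcl9 and Cxcl10 and the cytokine gene Il17a differed by 1.55, 1.39 and 1.24, and the estrogen-responsive list by a median of 0.07 (adjusted p = 0.713 with an estimated correlation), with Esr1 and Pgr at 0.15 and −0.06. Salivary gland genes were lower in 7 of 8 cases with a median of −0.48 (adjusted p = 0.706 with an estimated correlation). The mucin gene Muc5b stood at 2405 ± 1622 CPM in OVX and 6311 ± 3839 in Sham.

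Between OVXE2 and OVX, too, no gene and, with an estimated correlation, no list passed in gingiva. The values lay lower in OVXE2 for interferon-induced, T cell and dendritic cell genes and higher for glycolysis and muscle genes. In edgeR 0 of 12680 genes passed between OVXE2 and OVX (smallest adjusted p 0.108), 1766 had an unadjusted p under 0.05, DESeq2 called 48 higher and 44 lower and limma-voom 0. The kinase gene Pdk1, a brake on pyruvate oxidation, and the glycogen enzyme gene Pgm1 were 0.34 and 0.57 higher on the log2 scale, with adjusted p of 0.108 and 0.113. The chaperone gene Hsph1 differed by −0.44, at 89.0 ± 7.96 CPM (SD, n = 4) against 120 ± 10.1. Cxcl9 stood at 4.65 ± 2.15 CPM in OVXE2 and 40.2 ± 13.8 in OVX, with an adjusted p of 0.144, and the guanylate-binding protein gene Gbp2 at 18.8 ± 2.93 and 59.9 ± 16.5, with an adjusted p of 0.136. Without OVX 3, 11 genes were higher and 49 lower past the test, and 0 were so without any other single library. With replicate number as a block, or without the low-count filter, 2 genes passed.

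Of 41 lists in gingiva 3 were higher and 7 lower in OVXE2 than in OVX with a preset correlation, 0 with an estimated correlation and 1 with fry. The 10 lists became 17 without OVX 1 and 16 among the libraries of higher opposite-strand share. The 15 T cell and NK cell genes were all lower, with a median of −0.61 and 9 past the test when adjusted over the list alone (adjusted p = 0.225 with an estimated correlation and 0.0374 with fry). Without each library in turn the adjusted p with an estimated correlation ran from 0.0105, without OVX 2, to 0.622. It was below 0.05 for 1 of 12. The receptor genes Trac and Cd3g differed by −0.85 and −0.61. Interferon response genes were lower in 10 of 10 cases with a median of −0.65 and 4 past the test when adjusted over the list alone (adjusted p = 0.490 with an estimated correlation), Gbp3 among them with −0.96. Monocyte and macrophage genes were lower in 9 of 10 cases with a median of −0.43 and 6 past it (adjusted p = 0.593 with an estimated correlation), and dendritic cell genes in 5 of 7 with a median of −0.47 and 2 past it (adjusted p = 0.490 with an estimated correlation), Ccr7 with −1.06 and Cd209a with −1.32. Hypoxia and glycolysis genes were higher in 12 of 14 cases with a median of 0.17 and 1 past the test when adjusted over the list alone (adjusted p = 0.593 with an estimated correlation), Bnip3 with 0.49. Skeletal muscle genes were higher in 16 of 16 cases with a median of 1.41 (adjusted p = 0.593 with an estimated correlation). The myosin light chain gene Myl1 stood at 257 ± 113 CPM (SD, n = 4) in OVXE2 and 97.1 ± 37.5 in OVX, and the 16 muscle genes together at 0.526 ± 0.271% and 0.190 ± 0.115% of counts. Salivary gland genes were higher in 7 of 8 cases with a median of 0.93 (adjusted p = 0.593 with an estimated correlation). The estrogen-responsive list had a median of 0.01 (adjusted p = 0.975 with an estimated correlation), with Pgr and Esr1 at 0.18 and 0.07.

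Against Sham, no gene and, with an estimated correlation, no list passed in the gingiva of OVXE2 mice. In edgeR 0 of 12680 genes passed (smallest adjusted p 0.518), 939 had an unadjusted p under 0.05, DESeq2 called 6 higher and 2 lower and limma-voom 0. S100a8 stood at 1098 ± 161 CPM (SD, n = 4) in OVXE2 and 687 ± 94 in Sham, and S100a9 was 0.75 higher on the log2 scale. Hsph1 differed by −0.36, Pgm1 by 0.41, Cd209a by −1.17 and the urate oxidase gene Uox by 1.06. Of 41 lists 13 were higher and 7 lower with a preset correlation, and 0 passed with an estimated correlation or with fry. The sum of 20 lists was 12 without Sham 3 and 12 among the libraries of higher opposite-strand share. Skeletal muscle genes were higher in 16 of 16 cases with a median of 1.47 and 12 past the test when adjusted over the list alone (adjusted p = 0.272 with an estimated correlation). Mature neutrophil genes were higher in 12 of 13 cases with a median of 0.66 and 3 past it, and erythroid genes in 7 of 7 with a median of 0.69 and 5 past it (adjusted p = 0.272 with an estimated correlation for each). The haemoglobin gene Hba-a1 was 0.82 higher. Interferon response genes were lower in 10 of 10 cases with a median of −0.70 and 0 past the test when adjusted over the list alone (adjusted p = 0.331 with an estimated correlation). Dendritic cell genes were lower in 6 of 7 cases with a median of −0.56, 2 of them past the test when adjusted over the list alone (adjusted p = 0.272 with an estimated correlation). Endothelial genes were higher in 14 of 15 cases with a median of 0.24 (adjusted p = 0.580 with an estimated correlation). The cytokine gene Il17a stood at 1.63 ± 0.68 CPM in OVXE2 and 0.563 ± 0.351 in Sham, the estrogen-responsive list had a median of 0.15 (adjusted p = 0.585 with an estimated correlation), and Pgr and Esr1 differed by 0.11 and 0.22.

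**Figure D3:**
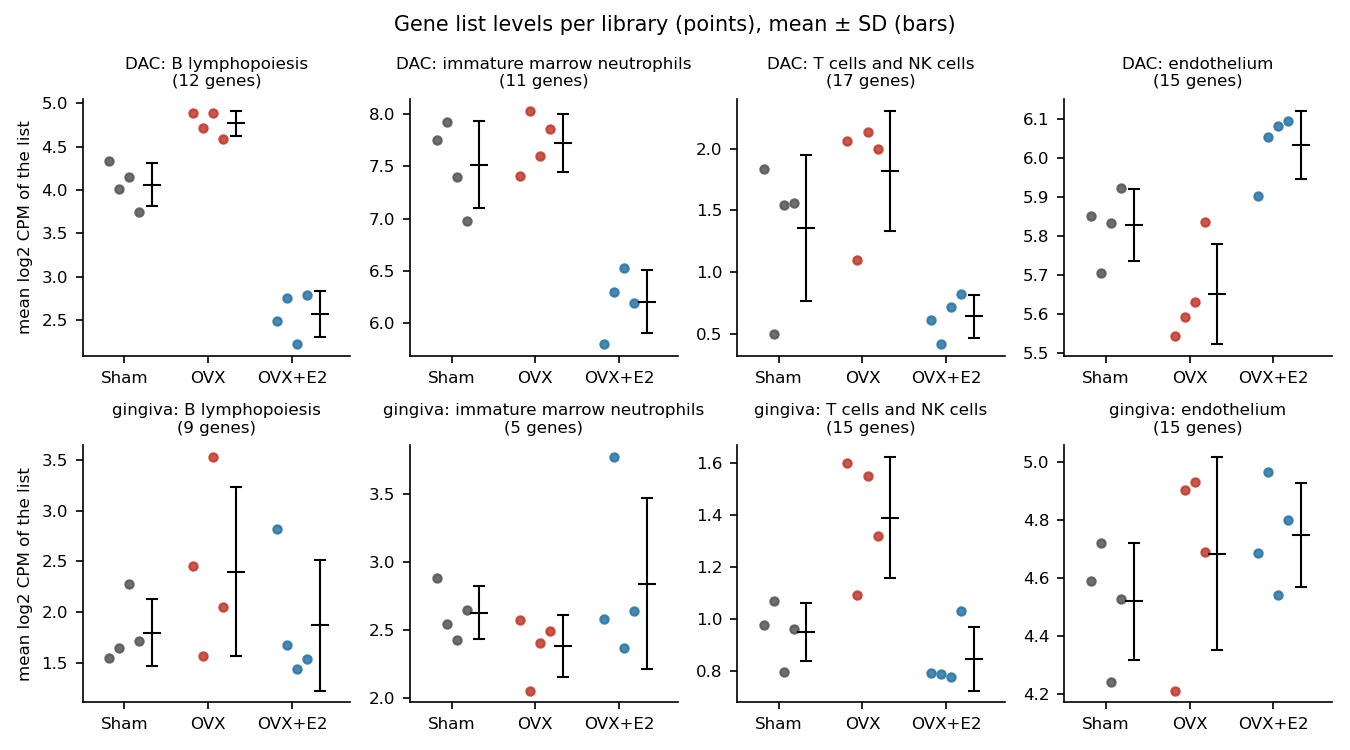
Mean log2 CPM of the members of 4 gene lists (B lymphopoiesis, immature marrow neutrophils, T cells and NK cells, endothelium) in each library, with the DAC in the upper and gingiva in the lower panels. Points are the 4 libraries of each group and bars their mean ± SD. In the DAC the B lymphopoiesis mean was 2.57 ± 0.266 in OVXE2, 4.77 ± 0.145 in OVX and 4.06 ± 0.248 in Sham, with no overlap between any pair of groups.

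By an exact permutation test of the mean level of each list, 6 of 42 lists in the DAC had no overlap between OVXE2 and OVX, where chance gives 2.86%, or 1.2 lists. They were B lymphopoiesis, mature B and plasma cells, immature marrow neutrophils, T cells and NK cells, dendritic cells, and, in the other direction, endothelium. Against Sham 5 lists of OVXE2 had no overlap, and between OVX and Sham 2 had none, B lymphopoiesis and salivary gland. In gingiva 3 of 41 lists had none in each of the comparisons, and T cells and NK cells stood apart in both comparisons with OVX. The smallest two-sided exact p that 4 against 4 libraries allow is 0.0286, and no list passed after Benjamini-Hochberg adjustment, with smallest values of 0.2 in the DAC and 0.293 in gingiva.

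Whether estradiol returned ovariectomized mice to the Sham state was examined over genes with an unadjusted p under 0.01 between OVX and Sham, since no gene passed there. In gingiva 97.8% of 314 such genes had opposite signs in the OVX against Sham and the OVXE2 against OVX comparisons. Both comparisons share the OVX libraries, and unchanged groups simulated with such sharing gave 92.7% (86.9 to 96.9%). Genes were drawn independently there, so this range is too narrow for genes that vary together. It cannot place 97.8% outside chance. The covariance of the log2 changes was −0.0599 against −0.0341 simulated. With the OVX libraries split between the comparisons, the share lay between 57.5 and 76.1% over the 6 ways to do so. In the DAC 90.1% of 71 genes had opposite signs against 91.6% simulated (86.6 to 96.6%), the covariance was −0.0562 against −0.0730, and the split OVX libraries gave 41.9 to 74.8%. Of genes called in the DAC against both OVX and Sham, 44 rose in both (of 92 and 53) and 87 fell in both (of 198 and 90). Independent lists of those sizes would share 0.358 and 1.31, too low a reference, since both comparisons use the OVXE2 libraries. Simulated unchanged groups shared 0, but each gene was drawn independently there, so few could pass and sharing was hardly possible. With the OVXE2 libraries split between the comparisons, 11 to 17 rising and 8 to 33 falling genes were shared.

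As a share of all variation over the 5000 most variable genes, the groups accounted for 24.8% in gingiva (permutation p = 0.0795) and 16.4% in the DAC (permutation p = 0.680). No pair of groups differed by this measure: the smallest exact permutation p was 0.143 in gingiva and 0.371 in the DAC. Without OVX 4 the share in gingiva was 28.9% with a permutation p of 0.0404.

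The effect of estradiol differed between the tissues in a small number of genes. The edgeR test of the difference between the OVXE2 against OVX effects of DAC and gingiva called 27 of 14209 genes, 10 with a higher and 17 with a lower effect in the DAC. Fam129c, a B cell gene (ENSMUSG00000043243, chromosome 8, 71597648 to 71607936), changed by −2.79 ± 0.24 (log2, SE) in the DAC and −0.20 ± 0.17 in gingiva, a difference of −2.58 ± 0.28 with an adjusted p of 6.05e-05. Trpc6 changed by 2.42 ± 0.20 in the DAC and 0.04 ± 0.18 in gingiva, and Pi15 by 3.34 ± 0.29 and 0.20 ± 0.24, with differences of 2.38 and 3.14. The peptidase gene Dpp4, Myb and the free fatty acid receptor gene Ffar2 differed by −2.14, −2.13 and −2.32, and the uncharacterized gene Fam78b by 1.19. Ifi209, Lrmp and Cecr2 differed by −1.50, −1.57 and −2.54. All 10 genes named here kept the call without each of the 24 libraries in turn. The count of 27 was 15 without gingiva OVXE2 1. It was 108 with DESeq2, 57 with limma-voom, 42 with a surrogate variable, 9 with a block for each group and replicate number and 2 among the libraries of higher opposite-strand share. For the OVX against Sham effect the same edgeR test called 0 of 14209 genes (smallest adjusted p 0.575), with 1212 at an unadjusted p under 0.05, as did DESeq2 and limma-voom. The smallest p included those of the gland genes Bpifb2, Gp2 and Muc5b, with differences of 4.42, 4.10 and 4.10, and those of Dpp4 and Trpc6, with 1.20 and −1.10.

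Across 12131 genes tested in both tissues, which are not independent replicates, the effects of OVX against Sham in DAC and gingiva had a Pearson r of −0.105 and a Spearman rho of −0.202 (exact permutation p = 0.743 over relabelled DAC libraries). Those of OVXE2 against OVX had 0.0204 and 0.0265 (exact permutation p = 1), and those of OVXE2 against Sham 0.0231 and 0.0737 (exact permutation p = 0.8). Of the 249 genes called between OVXE2 and OVX in the DAC that were also tested in gingiva, 201 had the same sign there: 71 of 84 that rose, with a median of 0.12 in gingiva, and 130 of 165 that fell, with a median of −0.20. By group means of log2 CPM the share with the same sign was 78.7%, with an exact permutation p of 0.0286, the smallest that 70 relabellings allow, and 73.5% in the highest other relabelling. For OVXE2 against Sham 80 of 115 had the same sign (69.6%, exact permutation p = 0.0857). These were 43 of 46 that rose, with a median of 0.27 in gingiva, and 37 of 69 that fell, with a median of −0.01.

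Sham DAC and Sham gingiva differed at most genes: 5636 of 14209 were higher in the DAC and 5037 lower in edgeR. With libraries of both tissues scaled together, Mpo stood at 304 ± 112 CPM (SD, n = 4) in the DAC and 0.353 ± 0.213 in gingiva, and Elane at 119 ± 41.4 and 0.104 ± 0.155, so that both were near the floor in gingiva. The eosinophil granule gene Prg2 was 10.11 higher on the log2 scale. Genes of nasal secretion led the DAC side as well: the odorant-binding proteins Obp2a and Obp1a were 10.36 and 9.97 higher and the lipocalin Lcn11 9.95, at levels that varied widely between libraries, such as 3251 ± 2063 CPM for Obp2a. The gingival side was led by cornifying epithelium and mucous glands. Filaggrin (Flg) stood at 0.533 ± 0.367 CPM in the DAC and 184 ± 24.3 in gingiva, the late cornified envelope gene Lce1a1 differed by −8.19 on the log2 scale, and Bpifb2 and Muc5b by −9.04 and −8.33. Of the called genes, 6394 had an estimated change of at least 2-fold.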

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

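The tests of the 3 patterns weighed in this part were chosen only after the results were seen; the splits of the libraries were planned. The tests for tissue of the nose or brain and for the split by other-strand share were changed after refits with fewer libraries had been seen; both are given. The gap of the farthest library to its nearest neighbour exceeded the critical share of the range by the Dixon test in 37 of 477 groups of 4, where chance gives about 1 in 20.

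Of library measures, gingiva Sham 3 had 19992438 gene counts (others 25068139 to 26001342). DAC OVX 1 had 0.495% unmapped fragments (others 0.591 to 0.602%), 13.5% mapped to several places (others 7.23 to 8.17%) and 0.881% ambiguous (others 1.04 to 1.05%). DAC OVXE2 3 had 1.04% unmapped (others 0.587 to 0.625%), and the most abundant gene of DAC OVXE2 2 held 7.75% of counts (others 6.04 to 6.24%). Outside the counts, the fragments mapped to several places in DAC OVX 1, 13.5%, exceeded the highest Sham library of the DAC, 9.15%, and the unmapped ones in DAC OVXE2 3, 1.04%, exceeded 0.696%.

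Of list means in log2 CPM, gingiva OVXE2 1 had 2.82 for B lymphopoiesis (others 1.44 to 1.67), DAC OVX 2 had 1.09 for T cells and NK cells (others 1.99 to 2.13) and gingiva OVXE2 4 had 1.03 (others 0.78 to 0.79). DAC Sham 1 had 6.37 for erythroid cells (others 5.26 to 5.44), gingiva OVX 1 had 2.12 for nasal glands (others 1.51 to 1.60) and DAC OVX 1 had 3.55 for peripheral ganglia (others −1.08 to −0.69).

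Of genes in the DAC, in CPM, OVX 3 stood apart for Bpifb2 (86.4, others 4.91 to 13.1), Muc5b (414, others 35.8 to 75.9), Gp2 (63.6, others 6.68 to 13.1) and Cd79a (59.2, others 33.2 to 34.9). OVX 1 did so for Dpp4 (18.8, others 11.2 to 12.3) and Rag1 (30.1, others 15.1 to 17.4), and OVX 4 for Il6 (8.54, others 5.16 to 5.6) and Rgs5 (530, others 488 to 494). OVXE2 1 did so for Flg (10.7, others 0.0450 to 0.842), Lce1a1 (29.4, others 0.27 to 1.08) and Mogat2 (0.668, others 1.00 to 1.05), OVXE2 3 for Cst7 (3.19, others 1.96 to 2.05) and OVXE2 4 for Fcrla (4.14, others 2.46 to 2.49). Sham 2 did so for Bpifb2 (3.01, others 3.48 to 3.56) and Sham 3 for Lif (24.6, others 19.2 to 20).

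In gingiva, Sham 3 stood apart for Cd3g (3.68, others 2.43 to 2.53), Lss (129, others 96.6 to 102) and, near the floor, Elane (0.300, others 0 to 0.0391) and Prg2 (0.1, others 0.0769 to 0.0798). OVX 2 did so for Erbb3 (150, others 165 to 166) and Pgr (18.3, others 23.6 to 24.6). OVXE2 2 did so for Trpc6 (1.69, others 1.44 to 1.47), OVXE2 3 for Fam129c (1.76, others 2.28 to 2.38), OVXE2 4 for Prg2 (0.123, others 0.0820 to 0.0835) and Sham 1 for Uox (55.6, others 27.8 to 31.0).

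The effect of OVXE2 against OVX differed between DAC and gingiva in 27 genes by the edgeR test of the difference. The log2 differences were −2.58 for Fam129c, 2.38 for Trpc6, 3.14 for Pi15, −2.14 for Dpp4, −2.13 for Myb, −1.50 for Ifi209, −1.57 for Lrmp, −2.32 for Ffar2, −2.54 for Cecr2 and 1.19 for Fam78b. Of 100 relabellings within each tissue only 1, the real one, gave as many genes (highest other 2). That is the smallest share 100 relabellings allow, so it goes against chance without excluding it.

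In the DAC of OVXE2 mice B lymphopoiesis genes were lower than in OVX, by a log2 difference of −2.20 in their mean. Beyond the erythroid and megakaryocyte means, themselves lower by −0.54 (exact permutation p = 0.0857), the list differed by −1.66 (exact permutation p = 0.0286, the smallest possible). A smaller share of marrow in the samples would lower all of these alike only if they came from marrow alone. Erythroid genes were also measured in gingiva, where Mpo was near the floor, so a smaller share of marrow was not excluded. With OVX 1, the library rich in nasal-gland transcripts, set apart the mean differed by −2.16 (exact permutation p = 0.0286). It differed by −2.24 within the sets of more and fewer brain neuron counts and by −2.16 within those of higher and lower other-strand share (exact permutation p = 0.0333 for each). The list had no overlap between the groups, so each p had to be the smallest possible and adds nothing. The difference kept its size, which argues against each of these as the whole cause. In refits the adjusted p with an estimated correlation was 0.0025 without Sham 2 and OVX 1, 0.0275 without the 4 libraries with most brain neuron counts and 0.0174 in the libraries of higher share (range over all alternatives 0.000116 to 0.0275). An effect of estradiol on B cell precursors of the marrow may explain the pattern and stays a hypothesis, since cell numbers were not measured.

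Immature neutrophil genes were lower in the same comparison, by −1.51 in their mean and by −0.97 beyond the erythroid and megakaryocyte means (exact permutation p = 0.0286, the smallest possible). For the reason given for B lymphopoiesis, this does not exclude a smaller share of marrow. The mean differed by −1.62 with OVX 1 set apart (exact permutation p = 0.0286). It differed by −1.42 within the sets by brain neuron counts and by −1.52 within those by other-strand share (exact permutation p = 0.0333 for each). Since the groups did not overlap for this list either, each p had to be the smallest possible. The difference kept its size, which argues against each of these as the whole cause. In refits the median, −1.60 with all libraries, was −1.71 without Sham 2 and OVX 1 (adjusted p = 0.00999 with an estimated correlation; range over all alternatives 0.00772 to 0.0727). It was −1.45 without the 4 libraries with most brain neuron counts (adjusted p = 0.0578) and −1.60 in the libraries of higher share (adjusted p = 0.0727), where the call ended at nearly the same size with fewer libraries. An effect of estradiol on immature neutrophils of the marrow may explain the pattern and stays a hypothesis as well.

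B lymphopoiesis genes were higher in the DAC of OVX than of Sham by a median of 0.76 (adjusted p = 0.0236 with an estimated correlation). Beyond the erythroid and megakaryocyte means they differed by 0.40 (exact permutation p = 0.171), while those means differed by 0.31 (exact permutation p = 0.257), so that a larger share of marrow in the OVX samples could explain the pattern. The mean of the list, higher by 0.71, differed by 0.67 with OVX 1 set apart (exact permutation p = 0.0286). Within the sets by other-strand share it differed by 0.75 (exact permutation p = 0.0333). As the groups did not overlap, both p had to be the smallest possible. The difference kept its size, which argues against tissue of the nose and that split as the whole cause. Within the sets by brain neuron counts the mean differed by 0.71, with an SD of 0.24 within sets (exact permutation p = 0.05, the smallest that so few libraries give). Both groups had equally many libraries in each of these sets, so that size had to equal the one over all libraries. It therefore says nothing for or against tissue of the brain as a cause. In refits the median was 0.72 without Sham 2 and OVX 1 (adjusted p = 0.147), 0.71 without the 4 libraries with most brain neuron counts (adjusted p = 0.449) and 0.62 in the libraries of higher share (adjusted p = 0.182; range over all alternatives 0.0217 to 0.449), where the call ended with fewer libraries.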

How the results depend on the processing

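The counts of either strand, the other-strand share as covariate or split, the pair and the 4 libraries left out together and the block for group and replicate number were chosen only after the results were seen. Of 10079 values of single genes under alternatives, 9443 stayed on the same side of the threshold, 565 lost and 71 gained the call. Uncalled genes, which cannot lose a call, are counted too. In the DAC 294 of 2235 values lost it for OVXE2 against OVX and 259 of 1798 for OVXE2 against Sham. Of the called genes that the naming rule gave, 15 of 55 and 5 of 40 there kept the call in every alternative with no single library left out. Of values called in either fit 0 reversed sign, while the sign of genes uncalled in both was not checked. List values were taken only for lists that passed with an estimated correlation or with fry. Of these 250 values 248 kept direction and side of the threshold with the preset correlation, and 2 gained the call. That correlation is the less strict one, and most of these lists lay far from its threshold. Over all lists the number past it moved when single libraries were left out, as given below. Unless stated, the cause was not tested.

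Genes past the test with DESeq2 were 44, 92 and 8 in gingiva (OVX against Sham, OVXE2 against OVX, OVXE2 against Sham; edgeR 0 each), 10, 598 and 340 in the DAC (edgeR 0, 290 and 143) and 108 for the difference between tissues under estradiol (edgeR 27). In the last 3 comparisons limma-voom gave 443, 337 and 57 and a surrogate variable 583, 279 and 42. A fit of the compared groups alone, with fewer libraries, gave 189 and 64 in the DAC. Of the genes edgeR called there, 147 of 290 and 74 of 143 had an estimated change of at least 2-fold. For the tissues in Sham 6394 of 10673 did. In gingiva 2 genes passed for OVXE2 against OVX without the low-count filter. With replicate number as a block also 2 passed there, and 250, 101 and 25 in the last 3 comparisons named for limma-voom; the block for group and replicate number gave 9 for the difference between tissues. Replicate numbers paired neither groups nor tissues (4 of 12 pairs in gingiva and 5 of 12 in the DAC above a correlation of 0.1). The other-strand share as covariate gave 62 for OVXE2 against Sham in the DAC, and the libraries of higher share alone, which are fewer, 39, 16 and 2. Without the 4 DAC libraries with most brain neuron counts, which leaves 2 of OVXE2, 37 and 10 genes passed in the last 2 comparisons of the DAC, and 12 lists for OVXE2 against OVX.

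Of the 290 genes DESeq2 called 290, limma-voom 280, the block 216 and the libraries of higher share 39. Gene lists past the test with an estimated correlation were 0, 0 and 0 in gingiva (15, 10 and 20 with the preset value) and 1, 5 and 3 in the DAC (20, 21 and 18), and with fry 0, 1, 0, 1, 8 and 4. The libraries of higher share gave 16 lists in gingiva for OVXE2 against OVX and 12 for OVXE2 against Sham. The B lymphopoiesis list had an adjusted p with an estimated correlation of 0.159 with replicate number as a block between OVX and Sham, and of 0.00293 between OVXE2 and OVX. With an estimated correlation further calls in the DAC were lost: between OVXE2 and OVX, in the libraries of higher share, those of endothelium (0.239), dendritic cells (0.173), mature B cells (0.101) and immature neutrophils (0.0727), and of endothelium also without both doubted libraries, Sham 2 and OVX 1 (0.0583). Between OVXE2 and Sham, those of immature neutrophils (0.0584) and mature B cells (0.0609) were lost with the block, and in the libraries of higher share (0.0657 and 0.324). That of B lymphopoiesis between OVX and Sham was lost in those libraries (0.182) and without both doubted libraries (0.147). Without the 4 libraries that of B lymphopoiesis was kept between OVXE2 and OVX (0.0275) and the other calls in the DAC were lost, with 0.449 for OVX against Sham, 0.0578 to 0.129 for OVXE2 against OVX, and 0.0765 to 0.106 for OVXE2 against Sham. With the OVX libraries divided between the comparisons, the share of opposite signs was 72.8, 57.5, 76.1, 70.6, 75.8 and 58.6% in gingiva (97.8% undivided) and 41.9, 57.7, 57.1, 60.3 and 53.8% in the DAC (90.1%), with 74.8% for 1 division; the shared libraries make such a drop by construction.

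Without each library in turn, genes past the test ranged from 0 to 0, 0 to 60 and 0 to 0 in gingiva, 0 to 0, 176 to 290 and 61 to 164 in the DAC, 0 to 0 and 15 to 33 for the differences between tissues and 10479 to 10995 for the tissues in Sham. Lists ranged from 10 to 17, 7 to 17 and 12 to 20 in gingiva and 13 to 22, 16 to 23 and 16 to 22 in the DAC. Opposite signs ranged from 94.6 to 99.8% in gingiva and 79.3 to 95.2% in the DAC, the correlation between tissues from −0.179 to 0.0733, and the group share from 23.1 to 28.9% in gingiva and 16.1 to 20.6% in the DAC. The value of 60 was that without gingiva OVX 3, 176 that without DAC OVXE2 4, 61 that without DAC Sham 1 and 15 that without gingiva OVXE2 1. Upper quartile scaling moved the median of all genes by 0.20 for the tissues in Sham. Depth and spread limit small changes: simulated 1.5-fold changes were recovered for 22.4 to 32.8% of genes in the DAC.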

Other observations

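The splits of the libraries in this part were planned, and none of its tests was chosen only after the result was seen, except for the marker lists of nasal glands, brain neurons and peripheral ganglia. In the DAC only 1 of 35 splits, the real one, gave as many genes as were called between OVXE2 and OVX (290, highest other split 45). So it was between OVXE2 and Sham (143, highest other 1). That is the smallest share 35 splits allow, unadjusted over the comparisons, so it goes against chance without excluding it. The same holds for the tissues in Sham (10673; highest other 0). Where edgeR called 0 genes every split gives as many, so the splits say nothing about chance there. This holds for OVX against Sham in the DAC (35 of 35 splits; 437 genes at an unadjusted p under 0.05; DESeq2 10; limma-voom 0), where the split of Sham 2, Sham 3, Sham 4 and OVX 1 from the rest called 65 genes and each other split 0. Such a count points to a structure of the libraries other than the groups. By mean log2 CPM the split follows the markers of peripheral ganglia, a list added after the data were examined. The mean was 0.44, 2.83, 3.83 and 3.55 in DAC Sham 2, DAC Sham 3, DAC Sham 4 and DAC OVX 1. It was −0.99, −0.69, −0.71 and −1.08 in DAC Sham 1, DAC OVX 2, DAC OVX 3 and DAC OVX 4. By their share of counts, given above, Sham 2 lay with the libraries of low values, so the match is partial. For gingiva, too, the splits say nothing about chance. There 35 of 35 splits gave as many genes in each comparison (highest other 1, 4 and 3). In edgeR 1530, 1766 and 939 genes had an unadjusted p under 0.05, while DESeq2 called 44, 92 and 8 and limma-voom 0. The same holds for the difference between tissues between OVX and Sham, with 100 of 100 relabellings (highest other 8). EdgeR called 0 genes there, as did DESeq2 and limma-voom, and in edgeR 1212 had an unadjusted p under 0.05.

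For the number of lists past the preset correlation chance could not be excluded in any comparison. In gingiva 14, 28 and 9 of 35 splits gave as many lists as the real 15, 10 and 20 (highest other 23, 22 and 25), and in the DAC 4, 12 and 6 of 35 as many as 20, 21 and 18 (highest other 25, 24 and 21).

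Markers of nasal glands took 4.15 ± 6.62% of counts (SD, n = 4; 0.231 to 14.0%) in DAC OVX, 1.73 ± 0.912% in DAC Sham and 0.727 ± 0.282% in DAC OVXE2. Markers of brain neurons took 0.0106, 0.0255 and 0.0147%, with the highest value, 0.0766%, in Sham.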
